A study of Homo sapiens with 8 samples.

How the data were processed

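GUIDE-seq libraries were made from HEK293T cells, which per the labels were electroporated with 4.5 μg of a plasmid for each target site, carrying Cas-SF01 and a crRNA, and with 1 nM of annealed tag oligonucleotide. Per the labels, 3 electroporations were pooled in 1 plate for each sample. Nothing in the labels says that replicates 1 and 2 were separate cultures, so the spread between these samples may be technical. Only the edgeR and DESeq2 p-values draw on that spread. Fisher's exact tests compare counts of molecules or loci and include no spread between samples. Coordinates are on hg38, per the submitters' processing notes. The aligner, the caller and their versions are not given in the sources used here.

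Each of the 8 files is a list of genomic windows. Per the file headers, the authors gave for each window and strand a count of molecules and a count of reads, as deposited without normalization, and counts of molecules for 2 primers. Columns were read by number because every row has 1 cell more than the header. In every row the sum over strands equalled the sum column, and molecules did not exceed reads. The deposited mismatch score of the authors was 1 below a recount in each full-length site, and stood at -1 for exact matches, so differences were recounted here. Windows have a 50-nt sequence. A window that a file does not list was counted as 0 where a number was needed, although it may have held molecules that were not listed.

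Results at other targets in these libraries are not reported here. Groups were taken from the number in the sample titles. The crRNA target of each number was read from the target column inside its files. The design fixed before the data were examined treated the 8 files as 8 libraries. Because files of numbers 2 to 4 were identical within a replicate, and the 2 control files differed by less than sampling noise, the planned permutation tests over 8 libraries (targets, gene lists and pairings of replicates) could not stand. They were replaced, after the data had been seen, by 2 crRNA libraries against 1 control library. The share of a target in the control is the mean of its 2 files, and its list of windows is that of replicate 1. The replicate 2 list was used as an alternative.

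Windows whose positions lay within 25 bp of each other were merged by single linkage into loci. On-target values sum the windows within 25 bp of the 23-nt target, and up to 4 windows can lie at 1 position. Intervals are exact (Clopper-Pearson) at 95% and cover counting error only. The largest libraries give the narrowest intervals, and replicate 2 had 15336 molecules against 83121 in replicate 1. Similar sites were searched in all window sequences on both strands, with 5'-TTN and up to 6 substitutions in 20 nt. This search found 100% of sites planted in 2400 simulated windows, and matched 0 of 6000 random ones. The planted sites lay whole inside the window, so sites that run past a window's end were not covered. The random windows used the 4 bases evenly, so the background in real windows was taken from shuffled and reversed crRNA sequences instead. Counts of molecules per locus were fitted with edgeR 4.0.16 (TMM, quasi-likelihood test, Benjamini-Hochberg adjustment) in R 4.3.3, with DESeq2 1.42.0 as an alternative. The fit had 1 residual degree of freedom. In data simulated for this comparison on 114 loci, 30 of them raised 64-fold, edgeR recovered 97.2% at a dispersion of 0.1, with 1.15 false calls on average. At the dispersion estimated here, 1.64, it recovered 0.684%, so a count of 0 calls has little weight. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

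Genes were named from RefSeq gene spans of the same build, which hold no exons. The gene lists were common fragile site genes, replication-dependent histone genes, snRNA and tRNA genes, the mitochondrial chromosome, hepatocyte secreted genes and genes in constant use. These were fixed before the data were examined. A list of mitochondrial pseudogenes was added afterwards. Loci were named by a rule fixed before the data were examined. It took each target, up to 10 other matched loci per crRNA, the 10 loci with the highest mean share of molecules, and up to 5 loci per direction past the threshold of the edgeR test. Examples from the authors' lists of similar sites, the fragile site genes, the recurrent loci and the loci called by alternatives were chosen after their values were seen.

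Alternatives covered the unit (reads), the distance, the denominator, a minimum of 10 molecules, the search settings, the tool and scaling, and each replicate left out. Testing against number 1 alone equals the comparison made, since the control was the only other library.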

Results

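Cas-SF01 is an engineered form of Cas12i3, a compact RNA-guided nuclease that cuts DNA next to a 5'-TTN flank. Its cutting across the genome was mapped in HEK293T cells, a human embryonic kidney line, by GUIDE-seq, in which a short double-stranded DNA tag is captured at breaks and the neighbouring genome is sequenced. Cells were collected at day 3, and the labels give 8 samples, numbered 1 to 4 in each of 2 replicates. The files of number 1 recorded a control with no target, and those of number 4 a target in TTR. Numbers 2, 3 and 4 of a replicate held the same windows with identical molecule and read counts, and differed only in the target that had been searched for. They were therefore counted as 1 library per replicate, called the crRNA library here. It is not known whether such a list is 1 pooled library searched for each target or the file of 1 sample given for all, and the series' design text names fewer gene targets than the files record. Shares below are of all molecules in a list, those at other targets included. The 2 control files shared 1786 identical windows and differed by less than the sampling noise (chi-square 57.5 on 1780 degrees of freedom), so they were counted as 1 sample. The comparisons below thus rest on 2 crRNA libraries and 1 control library.

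The replicate 1 crRNA library listed 1836 windows with 83121 molecules and 769899 reads. The replicate 2 crRNA library was smaller, with 363 windows, 15336 molecules and 38226 reads. The control files listed 1792 and 1795 windows, with 20874 and 20909 molecules. The median window held 2 molecules in the control and in replicate 1, and 3 in replicate 2. Every listed window had at least 1 molecule on each strand.

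The first comparison asked how much of the tag capture fell at the intended cut site in TTR, which encodes the thyroxine and retinol carrier transthyretin and lies on chromosome 18 (hg38). The TTR target took 47.7% of the molecules in replicate 1 (39669 molecules, 95% exact binomial interval 47.4 to 48.1) and 35.9% in replicate 2 (5513 molecules, 35.2 to 36.7). Their mean was 41.8% ± 8.33 (SD, n = 2), against 0.345% in the control, where the target held 72 molecules. It was the locus with the most molecules in both crRNA libraries and stood at rank 29 in the control. The exon or intron of the target was not analysed here.

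**Figure D1:**
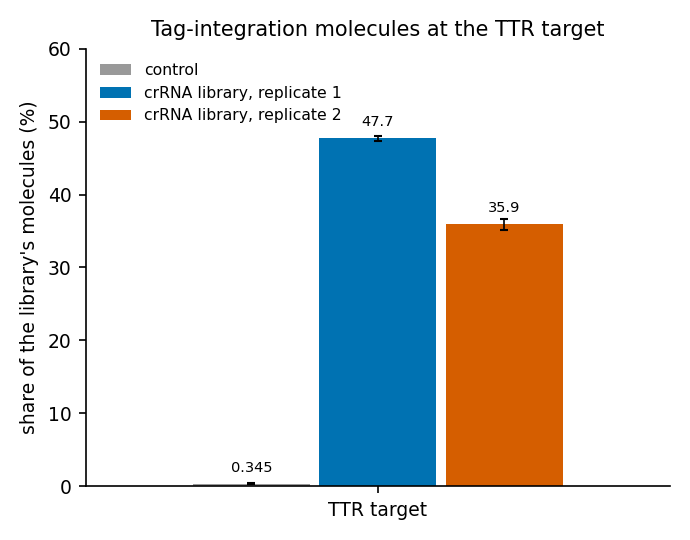
Share of each library's molecules (y axis, percent) in windows at the TTR target (x axis), with exact 95% binomial intervals; bars are the control (its replicate 1 file) and the 2 crRNA libraries. The crRNA libraries stood at 47.7% and 35.9%, and the control at 0.345%.

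Both crRNA libraries lay above the control at TTR, 138-fold and 104-fold. With 2 libraries against 1, a one-sided exact permutation test cannot go below p = 0.333, so that test cannot pass 0.05 here. Fisher's exact test of molecules, which compares single libraries and not conditions, gave p under 1e-300 for both. The TTR shares of the 2 crRNA libraries differed in molecules by more than counting error (Fisher's exact test, p = 1.35e-161). In reads they were 55.2% in replicate 1 and 57.4% in replicate 2, so the size and order of this difference depended on the unit.

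The second comparison asked for cutting at other sites that resemble the TTR crRNA. One such site stood out. It lies on the minus strand of chromosome 13 from 36228911 to 36228933, within CCDC169 and the readthrough gene CCDC169-SOHLH2. It differs from the TTR crRNA by 4 substitutions. Within 25 bp of it, 4 windows held 590 molecules and 1448 reads in replicate 1. That is 0.710% of that library (0.654 to 0.769) and 1.49% of the molecules at the TTR target. Of the 590 molecules, 465 lay on the plus strand and 125 on the minus strand. The search matched the site only in windows of 373 and 12 molecules, of which 372 and 10 lay on the plus strand. The rest of the 590 came from windows without a match in their own sequence. No window was listed there in the control or in replicate 2. At the same ratio to the TTR target, 82.0 molecules would have been due in replicate 2, and the 2 libraries differed in that ratio (Fisher's exact test, p = 1.67e-33). The site therefore rests on 1 library.

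The same search of every window, for 5'-TTN followed by up to 6 substitutions in the 20-nt protospacer, found 2 further TTR-like loci. One, with 6 substitutions, lies in DSC3 on chromosome 18 (31021760 to 31021782) and held 3 molecules in replicate 2. The other, also with 6, lies outside annotated genes on chromosome 21 (18784302 to 18784324) and held 2 molecules in replicate 1. In all, 3 of 2005 loci of the crRNA libraries outside the target matched the TTR crRNA, against 0 of 1573 in the control (Fisher's exact test, adjusted p = 0.782 over 3 crRNAs). The shuffled TTR sequence, used as a background, matched 2 loci of the crRNA libraries, so the 2 matches with 6 substitutions were no more than this background.

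The authors' own list of similar sites was longer, and held sites with more mismatches and with other flanks. It gave 14 sites outside the target for TTR in replicate 1, of which 9 began with TT, and 3 in replicate 2, of which 2 did. Apart from the chromosome 13 site, these windows held 2 to 9 molecules each. Among genes holding such windows in replicate 1 were RYR2, RAPGEF2 and UNC5D, each with 8 differences from the TTR crRNA over 23 nt, flank included, on recounting.

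The third comparison asked how far the libraries shared windows. Of 1641 loci in replicate 1, 101 were also in the control (6.15%, 5.04 to 7.43). Of 315 in replicate 2, 61 were in the control (19.4%, 15.1 to 24.2). The order of these shares turned when each library was thinned to the 363 windows with the most molecules. They were then 24.04% for replicate 1 and 14.4% for replicate 2, and the share of replicate 1 ranged from 1.17% to 24.04% over the settings tried. When replicate 2 was merged with replicate 1 instead, which gave 324 loci, 54 were in replicate 1 (16.7%, 12.8 to 21.2). Which of the 2 shares of replicate 2 was larger depended on the setting. At 5 bp they were 10.7% in the control and 10.95% in replicate 1, and without windows in mitochondrial pseudogenes and beside centromeres they were 2.87% and 3.69%. Over all 3 libraries, 46 of 3310 loci were listed in every one, among them the TTR target. Of the others, 28 lay in nuclear copies of mitochondrial genes, such as MTND5P11 within PCBD2 on chromosome 5 and MTND2P28, MTCO1P12 and MTCO2P12 on chromosome 1. A further 13 lay in blocks beside the centromeres of chromosomes 1, 3 and 16, which were picked out after the data had been seen. The chromosome 3 block held a locus at 93470374 with 2199 molecules in the control, 2047 in replicate 1 and 662 in replicate 2.

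By mean share over the 3 libraries, the 10 leading loci included TTR, which came first, the chromosome 3 block at 93470374, and a second locus of that block at 93470788, with 217 molecules in the control, 742 in replicate 2 and none listed in replicate 1. Another 5 of the 10 were listed in the control alone. They lay in LOC101928849 on chromosome 9 (118861049, 1045 molecules), outside genes on chromosome 13 (68844990, 967 molecules), in FRMD5 (963 molecules) and MAP2K5 (893 molecules) on chromosome 15, and outside genes on chromosome X (126074261, 882 molecules). In each of them at most 2 molecules lay on the rarer strand. Molecules at targets are part of the denominators, which lowers the share, and so the rank, of other loci in the crRNA libraries. In molecules, loci nearly all on 1 strand reached 1396 in replicate 1.

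Molecules per locus were then compared between the 2 crRNA libraries and the control over the 114 loci listed in at least 2 libraries. The fitted log2 fold change at TTR was 8.71 with TMM scaling and 6.92 without it, so its size depended on the scaling. No locus passed an adjusted p of 0.05 with edgeR's quasi-likelihood test, and 2 had an unadjusted p under 0.05. DESeq2 called 2 loci, TTR among them (adjusted p = 4.64e-06). Without TMM scaling, edgeR called 2 loci as well, again with TTR among them (adjusted p = 6.27e-11).

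The last comparison placed the loci among genes and chromosomes. Protein-coding genes held 45.5% of control loci (43.0 to 48.0), 45.4% in replicate 1 (43.0 to 47.8) and 42.1% in replicate 2 (36.7 to 47.7). Common fragile site genes, large late-replicating genes prone to breakage, held 16 of 1574 control loci (1.02%) and 15 of 1678 in replicate 1 (0.894%), close to the 1.07% of the genome span that these 25 genes cover. They included FHIT and MAGI2, with 3 loci each in replicate 1, and DMD, with 3 in the control. None of the 330 loci of replicate 2 lay in them. Neither crRNA library differed from the control in this list (Fisher's exact test, adjusted p of 1 and 0.491 over 18 comparisons). Copies of mitochondrial genes, a list added after the data had been seen, held 8.26% of control loci, 6.73% in replicate 1 (adjusted p = 0.491) and 16.1% in replicate 2 (Fisher's exact test, adjusted p = 0.000631). Among loci of at least 10 molecules the order turned, with 40 of 125 in the control, 17 of 102 in replicate 1 (16.7%) and 12 of 54 in replicate 2 (22.2%; replicate 2 against the control, Fisher's exact test, unadjusted p = 0.213). No locus lay in a histone, snRNA or tRNA gene, on the mitochondrial chromosome or in a gene in constant use such as ACTB or GAPDH. Whether windows on the mitochondrial chromosome could be listed is not given, so their absence may come from the processing. Among the hepatocyte secreted genes the only one with loci was TTR, the target itself, so this list repeats the cutting there. Of its 12 loci in replicate 1, 10 lay outside the target, and the control and replicate 2 had only the target's own.

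Of 23 chromosomes, chromosome 18, which carries TTR, held 60 loci in replicate 1 (3.58%) and 25 in the control (1.59%; Fisher's exact test, adjusted p = 0.00887). It held 9 loci in replicate 2 (2.73%, adjusted p = 0.646). Chromosome 16 held 11.8% of loci in replicate 2 and 4.07% in the control (Fisher's exact test, adjusted p = 6.77e-06), and 3.16% in replicate 1 (adjusted p = 0.615). The chromosome 16 count includes loci of the block beside its centromere, such as 46390718 with 91 molecules in replicate 2. Windows of the blocks beside centromeres were 13.2% of windows in replicate 2, 4.85% in the control and 3.21% in replicate 1. Whether the chromosome 16 difference remains without that block was not tested. These tests compare single libraries.

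**Figure D2:**
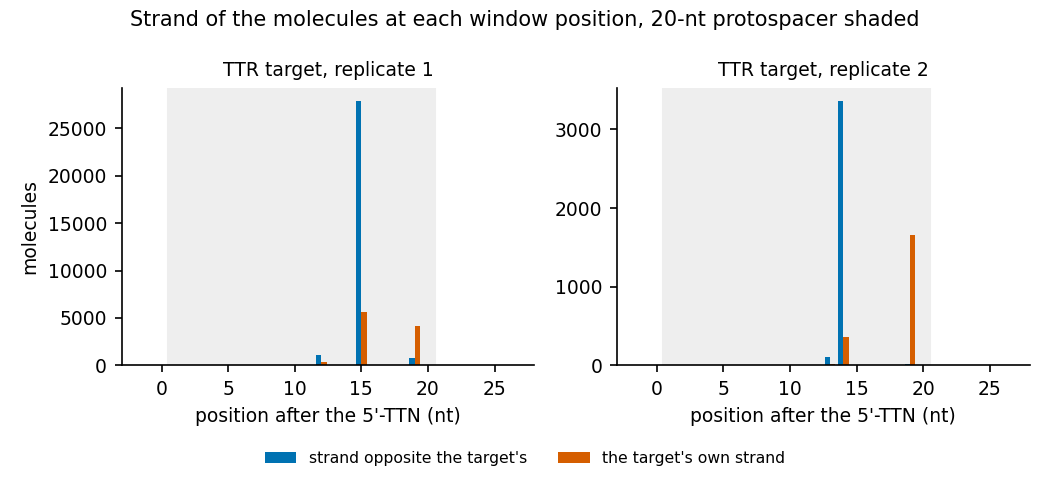
Molecules (y axis) by window position in nt after the 5'-TTN (x axis) at the TTR target in the 2 crRNA libraries, split by strand relative to the target, with the 20-nt protospacer shaded. In replicate 2 the strands' leading windows lay at 14 and 19, and in replicate 1 the window at 15 led for both strands.

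Within the TTR target, the main window of replicate 2 lay at position 14 after the flank, with 90.4% of its 3714 molecules on the strand opposite the target's, and the next at position 19, with 0.606% of 1650 molecules on it. In replicate 1 the main TTR window lay at 15 (83.3% of 33458 molecules) and the next at 19 (15.2% of 4821). There the window at 15 also held more molecules of the target's own strand (5586) than the window at 19 (4089). A 5-nt offset between the strands' leading windows was thus seen in replicate 2 only. Molecules are counted per window, so where each strand peaks inside a window is not known.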

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

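All tests in this part were chosen after the results were seen.

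The control held 72 molecules at the TTR target. Its window there lay at position 15 after the flank, as did the main window of replicate 1, while that of replicate 2 lay at 14. Carry-over from the replicate 1 library may be the source, and so may low-level cutting in the control's own cells. The latter would need the TTR crRNA in those cells. The labels do not name a control group, so whether its cells received any crRNA is not known. The target had 1 read per molecule in the control, and so did 14 of 66 other control windows of 10 to 100 molecules. Either explanation can give this position and this read count, so these values cannot tell the explanations apart.

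In replicate 1, 10 loci with 92 molecules lay between 26 bp and 1 kb from the TTR target, all on the side of its flank, at 113 to 796 bp before its start. None lay on the other side (two-sided exact binomial p = 0.00195), and none was listed in the control or in replicate 2. Spill of target molecules to both sides would place loci on both, if they are independent. The p-value restates the layout that prompted it, so it adds no separate support. At the density of the rest of chromosome 18, spread evenly, 0.00120 loci would be due within 1000 bp of the target, against the 10 listed. Lists of this size give under 1 locus in so small a space on any chromosome, and this space was picked because loci cluster there. An even background thus gives far fewer loci than were listed, and an uneven one was not tested. Deletions or rearrangements that start at the cut may leave tags on one side, which these files do not test.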

How the results depend on the processing

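Alternatives were planned before the data were examined, except the largest window, those without mitochondrial pseudogene and pericentromeric windows, the rank correlations over loci in both libraries, loci of all 3 libraries, and those for the mitochondrial pseudogene list. Of 53 settings over 13 results, 7 turned a direction, 3 in rank correlations and 4 in the mitochondrial pseudogene share against the control. Turns in other orders, as of the overlaps and of the 2 TTR shares in reads, were not counted.

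No paired analysis was possible because the crRNA files of a replicate are 1 library and the 2 control files are 1 library.

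The TTR share, 41.8%, was 56.3% in reads, 32.2% with the largest window, and 35.9% to 47.7% with a replicate left out. It was 60.1% when the 10 top loci, except TTR, left the denominator, which shrinks by construction. The cause of the rise in reads was not tested. All stayed above the control.

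The 3 TTR-matched loci became 1 with up to 4 substitutions or at least 10 molecules, 10 with any flank (5 in the control), 2 with the reversed and 2 with the shuffled sequence, and 1 or 2 with a replicate left out.

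The overlap of replicate 1 with the control, 6.15%, was 4.57% at 5 bp, 1.54% at 1000 bp, 14.6% at 10 molecules or more, 24.04% thinned to 363 windows, and 1.17% without mitochondrial pseudogene and pericentromeric windows. That of replicate 2 with the control, 19.4%, was 10.7%, 7.23%, 14.4% and 2.87% at 5 bp, at 1000 bp, thinned and without those windows. That of replicate 2 with replicate 1, 16.7%, was 10.95%, 6.05%, 11.6% and 3.69%. Loci merge at 1000 bp by construction, and the other causes were not tested. Over all merged loci the rank correlations were -0.738, -0.466 and -0.510, negative by construction as a locus must be listed in 1 of the 2; over loci in both they were 0.602, 0.386 and 0.479.

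The count of differing loci, 0, was 2 with DESeq2 and 2 without TMM, and 0 in reads, unfiltered and in loci of all 3 libraries. Without a library no residual degrees of freedom were left. The mean mitochondrial pseudogene share, 11.4% against 8.26% in the control, was 6.73% (without replicate 2) to 16.1% with a replicate left out. In molecules the mean and the control were both 4.87%, with 0.852% in replicate 1 and 8.88% in replicate 2. At 10 molecules or more it was 19.4%, and 22.2% in replicate 2, both below the control's 40 of 125 loci; the cause was not tested. The fragile site share, 0.447%, ranged from 0 to 0.894%. The depth of replicate 2 limits what its absences show.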

Other observations

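The tests in this part were chosen after the results were seen.

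The chromosome 13 site fits the TTR crRNA more closely if a gap is allowed. With 1 spacer base skipped, 1 substitution remains, in place of 4 without a gap. Sites with gaps were not searched elsewhere.

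Chromosome 18 carried more loci in replicate 1 than in the control, both close to TTR and far from it. Between 26 bp and 1 kb from the target there were 10 loci in replicate 1 and none in the control (Fisher's exact test, adjusted p = 0.0122 over 9 comparisons). From 1 kb to 10 Mb around the target there were 27 loci in replicate 1 and 19 in the control (Fisher's exact test, adjusted p = 0.616). On the rest of the chromosome there were 21 and 5 (adjusted p = 0.0122). Of the 27 loci, 26 held 2 molecules each. The 21 loci held 44 molecules in all, so they too lay near the least that a listed locus holds. Replicate 2 had none in the nearest range, 5 from 1 kb to 10 Mb and 3 on the rest, of 330 loci.

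Many windows were nearly all on 1 strand. Among loci of at least 50 molecules, 27 of 34 in the control had under 5% on the rarer strand, as did 15 of 31 in replicate 1 and 12 of 17 in replicate 2. Of the 27 in the control 1 was also listed in another library, of the 15 in replicate 1 none, and of the 12 in replicate 2 there were 2.

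SBK1 on chromosome 16 held 2 loci listed in both crRNA libraries and not in the control. At 28306339 they had 4 and 5 molecules, and at 28306426 they had 3 and 4. The search found no match to the TTR crRNA in them. Loci outside SBK1 had the same pattern, such as 90398550 on chromosome 2 (2 and 3 molecules) and 93470672 on chromosome 3 (1093 and 13).

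The files count molecules for 2 primers in columns that no comparison used. The TTR target held 453 such molecules in replicate 1 and 26 in replicate 2, which was 1.14% and 0.472% of its molecules. The control had none there, where 0.822 and 0.340 would have been due at those shares, so a difference was not detectable.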
